A study of Mus musculus with 12 samples.

How the data were processed

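RNA sequencing was carried out on C2C12 cells, a mouse myoblast line that differentiates into multinucleated muscle fibres when serum is lowered. Cells received a non-targeting siRNA (siControl) or an siRNA against Kctd10 (siKctd10), and were either undifferentiated (D0) or differentiating (D2). The 4 groups held 3 libraries each, 12 in all, and groups were taken from the labels. Per the labels' protocols, D0 cells were harvested 48 h after siRNA and stayed below confluence in medium with 10% serum, D2 cells were moved to medium with 2% horse serum 24 h after siRNA, and poly(A) RNA was sequenced. The protocols give 48 h of siRNA for all samples, which does not match 2 days in that medium, as the name D2 would give, so the time from siRNA to harvest at D2 is not settled. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

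The authors estimated transcript abundance with StringTie against a fixed set of 63759 known transcripts, per the file headers, which give version 1.3.3b. The submitters' processing notes name StringTie 1.1.3, HISAT, SAMtools, DESeq2 and the mouse build mm10, and which version made the values is not settled here. Per the file headers, each deposited transcript carries its coverage, FPKM and TPM, and TPM summed to 1000000 in every library. The deposited values are estimates and no deposited read counts were used here, so no count test gave the results, and voom on read pairs estimated from coverage was an alternative.

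Transcripts were matched to GENCODE genes on the same build (GRCm38, which is mm10) by identical introns (42629) or by at least 50% overlap of exon bases (13502). Matching failed for 7628, so that 88.0% were matched to 25796 genes, and unmatched transcripts held 3.82 to 4.62% of TPM per library. Gene TPM was the sum over a gene's transcripts. Genes with TPM of at least 1 in at least 3 libraries were kept (13075 genes), and 668 of these were listed at 0 in some library. The values log2(TPM + 1) were fitted with limma 3.58.1 (mean-variance trend, robust, 4 group means, 8 residual degrees of freedom), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. The comparisons were siKctd10 against siControl at D0 and at D2, D2 against D0 in each siRNA arm, and the interaction of day and siRNA.

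Depth was estimated from coverage and transcript length. Read pairs of 202 bases were inferred from the most frequent product of coverage and length, which gave 12.51 to 18.08 assigned read pairs per library in units of 1000000. The files give no counts per gene, so no counting interval was computed.

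The deposited estimates of genes with several transcripts could jump between replicates. Of genes with mean TPM of at least 5, 26.98% of 7427 genes with several or overlapping transcripts spread more than 3-fold inside some group, against 6.92% of 2904 genes with a single transcript that shared no exon base with another (called single-transcript genes here, 4025 of the kept genes). Values of the former are uncertain. The named genes of the single-transcript kind are Acta2, Ankrd1, Atp2a1, Capza1, Ccn2, Ccn3, Cd164, Cdh2, Cebpa, Cfl2, Chac1, Ckb, Ckm, Cnn2, Col4a2, Cxcl13, Cxcl5, Des, Dll1, Dpt, Fdft1, Gadd45b, Gbp2, Hey1, Heyl, Hrc, Hspd1, Ifit1, Kctd13, Mboat1, Mcm3, Msc, Myf5, Myl9, Mylpf, Myod1, Myog, Pdk4, Pgam2, Phex, Plet1, Prss37, Pygm, Rhob, Rplp1, Rrm1, Sfrp2, Tagln, Tubb3 and Ube2j1, and every other named gene has several or overlapping transcripts.

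A set of 28 gene lists was fixed before the data were examined, and 1 of them and some single genes are not reported here. The others were myogenic transcription factors, myoblast fusion, sarcomere, excitation-contraction and neuromuscular junction, muscle metabolism, protrusive and branched actin, SRF and MRTF targets, YAP and TEAD targets, KCTD family and CUL3 ligase, integrins and focal adhesion, proliferation, cell cycle exit, p53 targets, interferon response, ER stress and ATF4, cholesterol synthesis, extracellular matrix, TGF beta and BMP response, Notch pathway, markers of adipocytes, osteoblasts, smooth muscle, macrophages and leukocytes, and endothelial and neural cells, mitochondrially encoded genes, oxidative phosphorylation, and ribosomal proteins. They were tested with camera (limma) at a preset correlation of 0.01, and again with a correlation estimated per list and with fry, which asks whether a list's genes move, on balance, in 1 direction. Some genes stand in several lists.

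Named genes followed a rule also fixed before the data were examined. For siKctd10 at D0, at D2 and differentiation in siControl it took the 6 largest rises and 6 largest falls among genes past the threshold with no overlap between the groups and mean TPM of at least 5 in the higher group, leaving out predicted models and ribosomal protein genes. It added up to 4 called members of each called list, up to 2 members with the smallest adjusted p of each other list, the 6 interaction genes with the smallest adjusted p in each direction, and Kctd10, Kctd13, Tnfaip1, Cul3, Eps8, Baiap2, Rhob, Myod1, Myog, Mymk, Mymx, Myh3, Ckm and Acta1. The text gives the genes of this rule that matter most. Because many of the largest changes fell on genes with several transcripts, the largest-change and interaction parts were repeated over single-transcript genes with the same exceptions, a choice made after values were seen.

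The siRNA sequences were taken from the series' design text and matched to the reference transcripts. Matches to positions 2 to 8 of the guide strand were searched in the 3' UTRs of 12037 kept genes, and differences of medians were tested with 10000 permutations inside classes of 3' UTR length.

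Alternatives were pseudocounts of 0.1 and 5, no filter on low values, a filter of mean TPM of at least 5, FPKM in place of TPM, median-ratio scaling, quantile normalization, voom on estimated read pairs, only the groups compared in the fit, no trend and no robust fit, the replicate number as a block, an absolute log2 fold change of at least 1, camera with an estimated correlation, fry, and leaving out each library in turn. Single-transcript genes only, and leaving out both siKctd10 libraries numbered 3, were added after seeing the data.

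The fit was tested on simulated data in which a known set of the 13075 genes was changed (at D0, 92 genes by 1 and 108 by 2 on the log2 scale). At D0 it recovered 43.5% of genes with a log2 change of 1 and 77.8% with a change of 2, and 6.1% of calls were false. At D2 these shares were 40.6%, 75.5% and 2.6%, for differentiation in siControl 47.7%, 84.3% and 6.6%, for differentiation in siKctd10 38.1%, 80% and 4.1%, and for the interaction 28%, 73% and 1%. The simulation shuffled residuals gene by gene over all libraries, which removed links between genes and differences in noise between libraries. Its shares need not hold for the data, least of all for differentiation, where far more genes were called than were changed here. R 4.3.3, data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.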

Results

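Poly(A) RNA of 12 libraries of C2C12 myoblasts was compared in 4 groups of 3, formed by siRNA (siControl or siKctd10) and day (undifferentiated at D0, differentiating at D2). KCTD10 is a substrate adaptor of CUL3 ubiquitin ligases, and the series' title concerns ubiquitin-dependent remodelling of actin and cell fusion. The libraries held an estimated 12.51 to 18.08 assigned read pairs in units of 1000000, with 12021 to 12602 genes at a TPM of at least 1, and the 20 most abundant genes took 16.2 to 22.6% of TPM. The first principal component (41% of the variance) separated the days, and the second (10.4%) separated the siRNAs, with the siKctd10 libraries numbered 3 farthest out (42.0 at D0 and 42.2 at D2, against 1.3 to 20.7 for the other siKctd10 libraries). Replicates differed by more than sampling noise in every pair (chi-square per gene 12.74 to 63.19).

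Kctd10 was strongly reduced by its siRNA on both days. At D0 its TPM fell from 266 ± 7.32 to 23.1 ± 2.69 (SD, n = 3 each), leaving 8.7%, with a log2 fold change of -3.48 (SE 0.11, limma adjusted p = 6.8e-07). At D2 it fell from 283 ± 6.77 to 32 ± 4.58, leaving 11.3%, with a log2 fold change of -3.12 (SE 0.11, limma adjusted p = 1.7e-06). Every siKctd10 library lay below every siControl library of its day, and the two-sided exact permutation test gave p = 0.1 on each day, the smallest that 3 against 3 allows. The siRNA sense strand CCAGCAAUUCUGACGAUAA matched the Kctd10 coding sequence on the minus strand of chromosome 5 (GRCm38/mm10), between 114367390 and 114368345. The match spanned the junction of exon 5 (4 bases, from 114368342) and exon 6 (15 bases, to 114367404) in ENSMUST00000001125.5 and ENSMUST00000102581.10. Kctd10 itself did not pass the test between days in siControl cells (log2 fold change 0.09, adjusted p = 0.59).

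**Figure D1:**
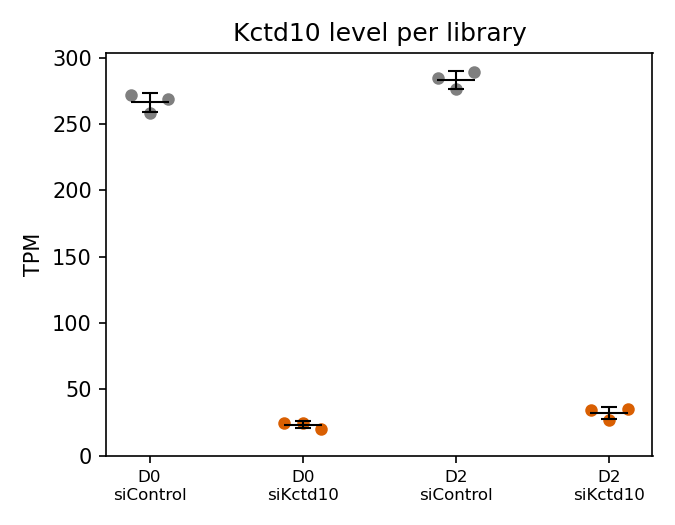
TPM of Kctd10 in each of the 12 libraries (points), with the mean and SD of the 3 libraries of each group (bars). The siKctd10 libraries averaged 23.1 at D0 and 32 at D2, against 266 and 283 in siControl.

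The first comparison asked what differentiation did in siControl cells. Muscle genes rose steeply and cell cycle genes fell. Of 44 sarcomere genes 41 rose and none fell (41 adjusted over the list alone), with a median log2 fold change of 3.73. Mylpf, the fast regulatory myosin light chain, rose from 5.12 ± 4.11 to 1170 ± 66.3 TPM, and Myh3, embryonic myosin heavy chain, from 2.53 ± 1.03 to 324 ± 21.7 (SD, n = 3 each). Myog, a myogenic transcription factor, rose from 12.1 ± 2.09 to 324 ± 36.8 TPM (log2 fold change 4.64), and the fusion proteins Mymk and Mymx rose by 4.96 and 4.85 on the log2 scale. Of 47 proliferation genes 34 fell and none rose, with a median of -1.24, among them the replication helicase subunits Mcm5 (-2.32) and Mcm3 (-2.06).

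Other muscle lists moved with the sarcomere. Of 23 genes of excitation-contraction coupling and the neuromuscular junction 21 rose (21 adjusted over the list alone, median 2.54), led by the acetylcholine receptor subunit Chrng (5.54) and the calcium pump Atp2a1 (4.99). Of 13 myogenic transcription factors 9 rose (11 adjusted over the list alone, median 0.76), including Myod1 (75.2 ± 0.836 to 245 ± 7.73 TPM, log2 fold change 1.69) and Mef2c (2.23). Of 10 muscle metabolism genes 7 rose (7 adjusted over the list alone, median 2.35), including Pgam2 (3.35), and the creatine kinase Ckm was listed at 0 in each D0 siControl library and reached 40.4 ± 6.46 TPM at D2. Of 36 extracellular matrix genes 26 rose and 1 fell (26 and 2 adjusted over the list alone, median 1.05), among them the proteoglycan Dcn (14.6 ± 2.18 to 566 ± 15.9 TPM). Of 14 Notch pathway genes 10 rose (10 adjusted over the list alone, median 0.75), led by Heyl (3.76) and the ligand Dll1 (2.98). Of 11 smooth muscle markers 8 rose (8 adjusted over the list alone, median 1.54). The members that moved most, Pdlim3 (4.47), Ldb3 (2.22) and Des (1.72), are also made by skeletal muscle. Of 22 interferon response genes 11 rose (12 adjusted over the list alone, median 0.62), including Gbp2 (1.89). Of 37 ribosomal protein genes 16 fell and 1 rose (17 and 1 adjusted over the list alone, median -0.48), including Rplp1 (-1.19). For proliferation, 36 fell adjusted over the list alone.

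In all, limma called 4636 of 13075 genes for differentiation in siControl, 2803 higher and 1833 lower, and 4589 of them had no overlap between the groups (52.3% of all genes had none, against 10% by chance for 3 against 3). Median-ratio scaling called 4692 genes with 52% higher and quantile normalization 4524 with 49% higher, against 60.5% here, and the median of all genes moved from 0.091 to 0.006 and -0.033. Camera called 10 of 28 lists by adjusted p as rounded here. The adjusted p was 7.7e-24 for sarcomere, 1e-14 for excitation-contraction, 1.4e-05 for myogenic transcription factors, 4.8e-18 for proliferation, 1.3e-08 for extracellular matrix, 1.3e-05 for Notch and 8.5e-05 for smooth muscle markers, and these 7 were also called with an estimated correlation. It was 6e-05 for muscle metabolism (adjusted p = 0.087 with an estimated correlation), 0.0046 for interferon response (adjusted p = 0.11 with an estimated correlation) and 1e-05 for ribosomal proteins (adjusted p = 0.1 with an estimated correlation). The myoblast fusion list lay at the threshold and was not counted (camera adjusted p = 0.05 as rounded, adjusted p = 0.24 with an estimated correlation). Fry called it upward (adjusted p = 3.9e-07). In it 12 of 29 genes were higher and 2 lower over all genes as over the list alone. Medium, density and day changed together and cannot be separated.

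The next comparison asked what loss of Kctd10 did in undifferentiated cells. Tagln, an actin-bundling protein, rose from 56.2 ± 6.54 to 149 ± 9.51 TPM (log2 fold change 1.40, SE 0.11, limma adjusted p = 0.00027), smooth muscle actin Acta2 from 600 ± 52.3 to 1560 ± 139 (1.38), and the myosin light chain Myl9 from 73.9 ± 2.13 to 177 ± 27.2 (1.24). Capza1, a subunit of the protein that caps actin filaments, fell from 189 ± 10.8 to 48.5 ± 10 TPM (-1.96, SE 0.16, adjusted p = 0.00028), and Mboat1, a phospholipid acyltransferase, from 42.8 ± 1.08 to 7.37 ± 1.36 (-2.40).

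Of 24 cholesterol synthesis genes 8 rose and none fell (12 rose adjusted over the list alone, median 0.48), among them Fdft1 (0.60) and Msmo1 (0.59). The camera adjusted p was 1.7e-09 (adjusted p = 0.062 with an estimated correlation). Of 21 YAP and TEAD targets 5 rose and none fell (12 rose and 1 fell adjusted over the list alone, median 0.53), among them Ankrd1 (470 ± 13.3 to 959 ± 214 TPM, log2 fold change 1.00), Lats2 (0.87), Gadd45b (0.81) and Ccn2 (0.75). Camera gave adjusted p = 5e-07, and adjusted p = 0.0087 with an estimated correlation. Of 11 smooth muscle markers 2 rose, Tagln and Acta2 (6 rose adjusted over the list alone, median 0.70), with camera adjusted p = 9.4e-06, and adjusted p = 0.013 with an estimated correlation. Of 29 SRF and MRTF targets, genes driven by actin-regulated transcription, 5 rose (9 rose and 2 fell adjusted over the list alone, median 0.17), including Tagln, Acta2, Myl9 and Cnn2 (0.66). Here camera gave adjusted p = 0.011 (adjusted p = 0.062 with an estimated correlation). Of 37 ribosomal protein genes 2 fell, including Rplp1 (-0.88, with 3 lower adjusted over the list alone and a median of -0.16), with camera adjusted p = 5.9e-05 (adjusted p = 0.24 with an estimated correlation).

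Single genes of lists that were not called also passed. Cd164, a sialomucin of the fusion list, fell from 743 ± 40.8 to 362 ± 25.9 TPM (-1.04), the myogenic repressor Msc by -1.09, the creatine kinase Ckb by -0.99 and the tubulin Tubb3 by -0.92. The collagen Col4a2 (0.90), the integrin Itga3 (0.86, 3 transcripts) and skeletal actin Acta1 (0.94, 2 transcripts) rose. The other large falls were Prss37 (-2.02), Plet1 (-1.74) and Stmn4 (-3.37, 3 transcripts). The largest rises, Ppia (5.84), Wbp1l (3.60), Uevld (3.45), Sp1 (2.55), Fblim1 (2.13) and Puf60 (1.96), all fell on genes with several transcripts, whose estimates are uncertain. Of the protrusive and branched actin list only Capza1 passed among 47 measured genes (1 adjusted over the list alone, adjusted p = 0.67 for the list). The muscle regulators Myod1 (0.08), Myog (-0.23), Mymk (-0.40) and Mymx (-0.20) did not pass, nor did Kctd13, Tnfaip1, Cul3, Eps8, Baiap2 or Rhob (-0.33, adjusted p = 0.1).

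In all, genes changed by siKctd10 at D0 numbered 320 by limma, 194 higher and 126 lower, each with no overlap between the 3 and 3 libraries, while 23.2% of all genes had none (10% by chance). The higher share was 60.6%, but 47.6% of 395 genes after median-ratio scaling and 47.5% of 305 after quantile normalization. The count was 118, 135 and 173 without the D0 siControl library numbered 1, 2 and 3, 208 and 166 without the D0 siKctd10 library numbered 1 and 2, and 72 with only the D0 groups in the fit. Of the 5 lists called, the SRF and MRTF targets lost their call with the filter of mean TPM of at least 5 (adjusted p = 0.053) and without the D0 siKctd10 library numbered 1 (adjusted p = 0.056), and ribosomal proteins lost theirs with fry (adjusted p = 0.059).

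At D2, cells with siKctd10 held less of the muscle programme than siControl cells. Myog fell from 324 ± 36.8 to 192 ± 20.8 TPM (log2 fold change -0.75, SE 0.14, limma adjusted p = 0.016, n = 3 each), Myod1 from 245 ± 7.73 to 190 ± 10.4 (-0.37, SE 0.06, adjusted p = 0.0091), and the fusion protein Mymk from 175 ± 23.3 to 91.7 ± 8.79 (-0.92, SE 0.16, adjusted p = 0.012). Atp2a1, the calcium pump of the sarcoplasmic reticulum, fell from 99.6 ± 9.22 to 39.1 ± 11.1 TPM (-1.36). Of 44 sarcomere genes 11 fell and none rose (19 fell adjusted over the list alone, median -0.62). They included Myh8, perinatal myosin (-1.53, 8 transcripts), Tnni1 (-2.03, 4 transcripts), Myoz2 (-1.38, 2 transcripts) and the filament-end capping protein Tmod1 (-3.77, 2 transcripts).

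The camera adjusted p of the sarcomere list was 1.2e-15 (adjusted p = 0.069 with an estimated correlation). Of 13 myogenic transcription factors 5 fell (6 adjusted over the list alone, median -0.25), among them Myf5 (-0.57), Mef2c (-1.54, 7 transcripts) and Msc (-1.64), with adjusted p = 1.3e-05 (adjusted p = 0.069 with an estimated correlation). Msc is a repressor, was already lower at D0 (-1.09), and its interaction did not pass (-0.55, limma adjusted p = 0.6). Of 23 genes of excitation-contraction coupling and the neuromuscular junction 5 fell (6 adjusted over the list alone, median -0.25), including Casq1 (-1.58), Dok7 (-0.89) and Hrc (-0.81), with adjusted p = 3.1e-05 (adjusted p = 0.069 with an estimated correlation). In the list excitation-contraction and neuromuscular junction, D2 medians were -0.12 and -0.47 without the D2 siKctd10 library numbered 1 and 2, and -0.16 and -0.40 without the D2 siControl library numbered 2 and 3, and camera called it each time. Of 10 muscle metabolism genes 4 fell (5 adjusted over the list alone, median -0.54), including Pgam2 (-1.31), Pygm (-1.11) and Ckb (-1.03), with adjusted p = 0.00015 (adjusted p = 0.14 with an estimated correlation). In the myoblast fusion list Mymk, Cd164 (-0.80) and Ccdc141 (-0.64) fell and the cadherin Cdh2 rose (0.45) among 29 genes (3 fell and 2 rose adjusted over the list alone, median -0.13), with adjusted p = 0.035 (adjusted p = 0.22 with an estimated correlation). Cd164 and Ccdc141 were already lower at D0 (-1.04 and -0.75). Their 3' UTRs hold matches of 7 and 6 bases to the seed of the siKctd10 guide strand, so off-target repression may contribute to these falls. Of the muscle genes that the rule always named, those that did not pass were Mymx (-0.63, adjusted p = 0.23), Ckm (-0.88, adjusted p = 0.06), Acta1 (-0.59, adjusted p = 0.065) and Myh3 (-0.08, adjusted p = 0.95). In the sarcomere list 33 of 44 genes were not called.

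Of 36 extracellular matrix genes 7 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.15), with rises of Thbs1 (1.46, 2 transcripts), Col12a1 (1.31) and Col4a2 (0.70) and a fall of Dcn (-0.68). Its camera adjusted p was 0.018 (adjusted p = 0.25 with an estimated correlation). Of 28 genes of ER stress and ATF4 signalling 3 rose (3 adjusted over the list alone, median 0.30), namely Sesn2 (1.74), Chac1 (0.80) and the transcription factor Atf4 itself (0.56), with adjusted p = 0.042 (adjusted p = 0.15 with an estimated correlation). Of 21 YAP and TEAD targets 8 rose and 2 fell (10 and 2 adjusted over the list alone, median 0.42), with adjusted p = 0.011 (adjusted p = 0.072 with an estimated correlation). Amotl2 (0.94), Asap1 (0.79) and Lats2 (0.77) rose, while Ccn2 fell from 136 ± 4.47 to 76.8 ± 3.37 TPM (-0.81). Ribosomal proteins were lower as a list, with 1 of 37 members called (1 adjusted over the list alone, median -0.22, adjusted p = 0.0016, and adjusted p = 0.22 with an estimated correlation). Oxidative phosphorylation was lower as a list with none of 30 members called over all genes or over the list alone (median -0.16, adjusted p = 0.018, and adjusted p = 0.21 with an estimated correlation). Of 47 proliferation genes Rrm1 rose (0.75) and Cdc25b fell (-0.46), the same counts adjusted over the list alone (median -0.06, adjusted p = 0.041, and adjusted p = 0.2 with an estimated correlation).

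Among other genes Ccn3, a matricellular protein, fell from 225 ± 2.09 to 40.4 ± 2.27 TPM (-2.45), the chemokine Cxcl13 from 62.5 ± 3.83 to 11.7 ± 1.78 (-2.33), and Capza1 from 204 ± 39.4 to 75.8 ± 3.05 (-1.40). Among single-transcript genes Cxcl5 rose from 13.6 ± 0.396 to 49.9 ± 7.19 TPM, Pdk4, which restrains pyruvate use, from 20.8 ± 1.98 to 61 ± 2.56, and the Wnt antagonist Sfrp2 from 32.9 ± 2.6 to 86.8 ± 7.56. Acta2 (0.91), Myl9 (0.82) and Tagln (0.68) rose at D2 too, although the SRF and MRTF list (6 of 29 higher, 6 adjusted over the list alone, adjusted p = 0.062) and the smooth muscle list (adjusted p = 0.85) did not pass with camera. Of 11 smooth muscle markers 2 rose and 2, Ldb3 (-0.66) and Pdlim3 (-0.68), fell at D2 (3 and 2 adjusted over the list alone). With fry, which does not compare a list with other genes, the SRF and MRTF list passed upward (adjusted p = 0.00011). The largest rises, Stk38l (5.25), H2afv (4.32), Pdpk1 (3.74), Cdkn2aip (3.03), Asxl1 (3.01) and Uevld (2.69), and the falls of Ap3s1 (-6.32) and Zbtb25 (-3.69), fell on genes with several transcripts and are uncertain.

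In all, genes changed by siKctd10 at D2 numbered 622 by limma, 370 higher and 252 lower, each with no overlap between the 3 and 3 libraries, while 28.4% of all genes had none (10% by chance). The higher share was 59.5%, but 39.4% of 673 genes after median-ratio scaling and 46.5% of 636 after quantile normalization. The count was 316 and 350 without the D2 siControl library numbered 1 and 2, 369, 407 and 377 without the D2 siKctd10 library numbered 1, 2 and 3, and 263 with only the D2 groups in the fit. Of the 11 lists called, myoblast fusion, oxidative phosphorylation, proliferation, extracellular matrix, ER stress and ATF4, and ribosomal proteins (adjusted p = 0.17 with fry) lost their call under at least 1 alternative or without 1 library, and none was called with an estimated correlation.

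**Figure D2:**
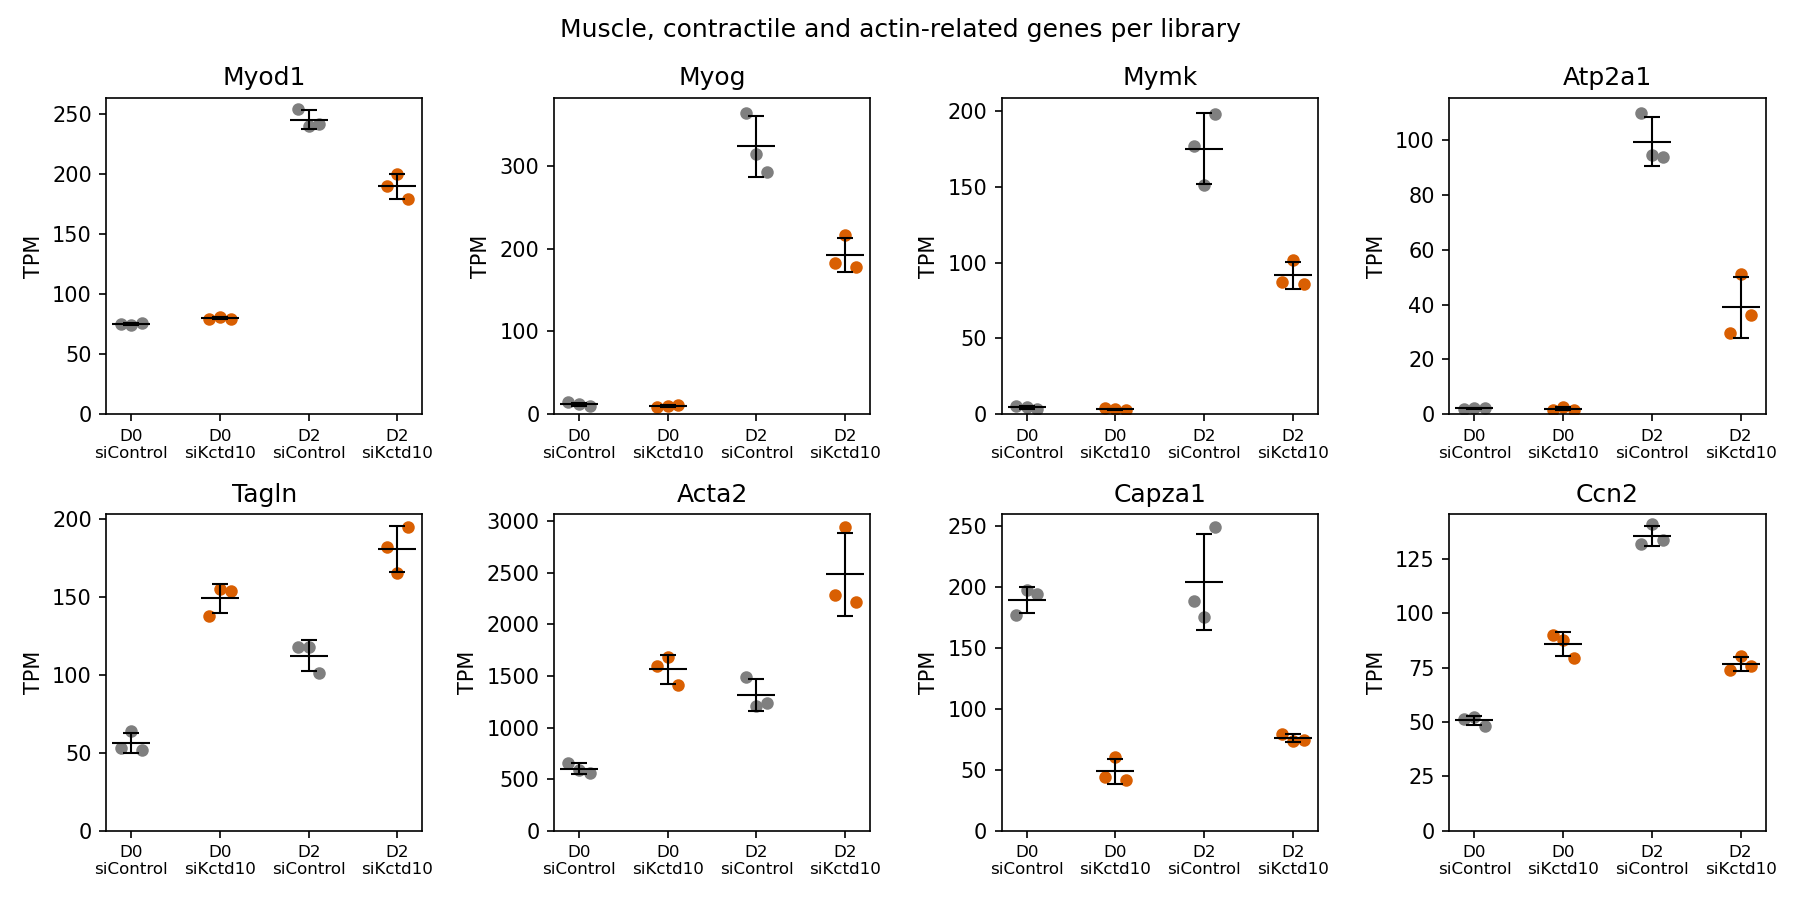
TPM of 8 genes in each of the 12 libraries (points), with the mean and SD of each group of 3 (bars), each panel on its own axis from 0. At D2, Myog averaged 324 in siControl and 192 in siKctd10, and at D0 Tagln averaged 56.2 and 149.

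**Figure D3:**
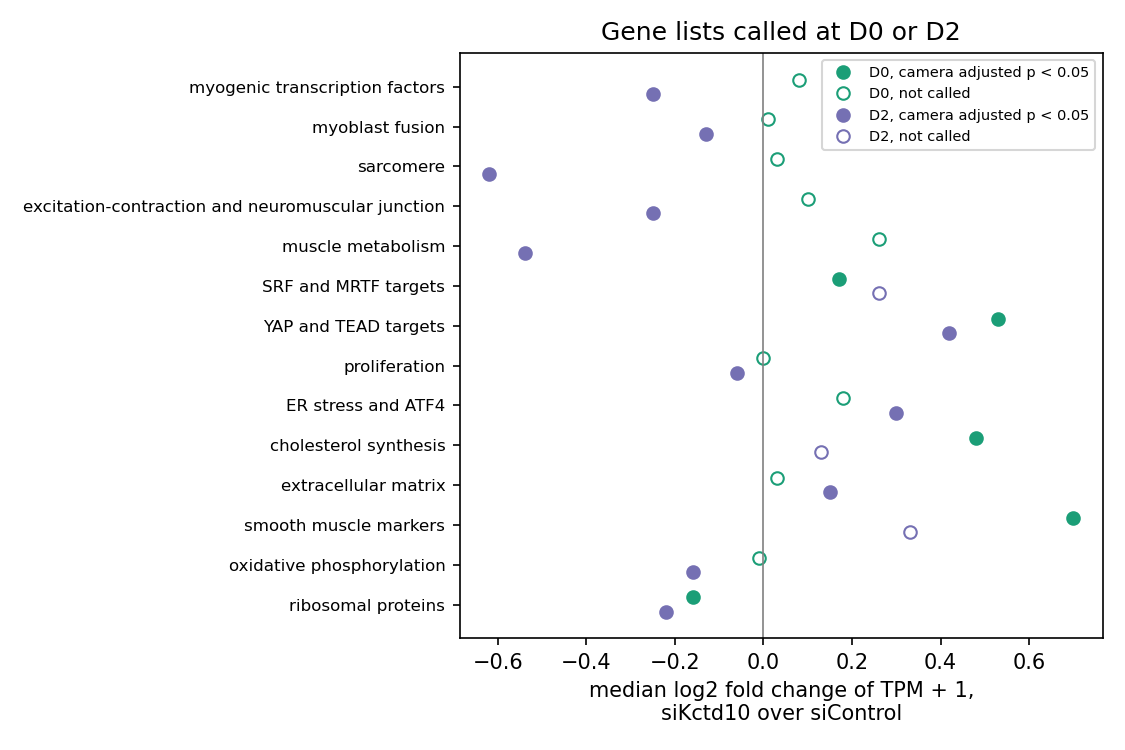
Median log2 fold change of TPM + 1, siKctd10 over siControl, of each list that camera called on at least 1 day, with filled points where the adjusted p was under 0.05 and open points where it was not. The sarcomere median was -0.62 at D2 and 0.03 at D0, and the smooth muscle median was 0.70 at D0.

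Differentiation was also compared between the siRNA arms. In siKctd10 cells muscle genes still rose, but by less. Of 44 sarcomere genes 38 rose with a median log2 fold change of 2.72, against 3.73 in siControl, and 41 of the 44 rose less in siKctd10. The medians were 1.82 against 2.54 for excitation-contraction and the neuromuscular junction (20 of 23 rose less) and 0.51 against 0.76 for myogenic transcription factors (12 of 13). Myog rose from 10.1 ± 0.936 to 192 ± 20.8 TPM in siKctd10 cells and Myod1 from 79.7 ± 0.844 to 190 ± 10.4. Skeletal actin Acta1 rose by 2.44 in siKctd10 and by 3.97 in siControl, a difference of -1.53 (SE 0.22, adjusted p = 0.016, 2 transcripts). The larger part of this difference came from its higher level after siKctd10 at D0 (0.94, limma adjusted p = 0.017). Its fall at D2 did not pass (-0.59, limma adjusted p = 0.065). Proliferation genes fell alike in number, 36 of 47 against 34, with medians of -1.31 and -1.24.

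The interaction test gave adjusted p = 7.6e-17 for the sarcomere list (median -0.75, 4 lower, 13 adjusted over the list alone, adjusted p = 0.052 with an estimated correlation). It gave 3.3e-09 for excitation-contraction and the neuromuscular junction (median -0.60, 1 lower, 8 adjusted over the list alone, adjusted p = 0.015 with an estimated correlation) and 1.6e-05 for myogenic transcription factors (median -0.41, 4 lower adjusted over the list alone, adjusted p = 0.052 with an estimated correlation). The proliferation list showed no interaction past the threshold (median -0.03, adjusted p = 0.55). For single genes limma called 101 interactions, 49 higher and 52 lower, and the difference did not pass for Myod1 (-0.45, adjusted p = 0.05), Myog (-0.52, adjusted p = 0.39) or Mymk (-0.53, adjusted p = 0.48). In siKctd10 cells 4755 genes changed with differentiation, 3022 higher and 1733 lower (63.6% higher, 51.8% of 4733 after median-ratio scaling and 50.4% of 4511 after quantile normalization), and the median of all genes moved from 0.118 to 0.003 and -0.021. The share of interactions that was higher was 48.5%, against 38.1% of 134 and 44.9% of 107 under these scalings, and the interaction count lay between 57 and 168 over the other settings and left-out libraries without a block.

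The effects of siKctd10 on the 2 days were related. Of the genes called, 78 were higher on both days (5.5 by chance for independent lists), 42 were lower on both (2.4 by chance) and 4 went opposite ways, and 86.6% of genes called at D0 had the same sign at D2. Genes lower on both days included Capza1, Mboat1, Cd164, Ckb and Msc, and genes higher on both included Tagln, Acta2, Myl9 and Col4a2. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.20 and Spearman's rho 0.27, and r was 0.32 over single-transcript genes and 0.12 without both siKctd10 libraries numbered 3. The 2 comparisons share no library. Of 2803 genes that rose with differentiation in siControl, 208 were lower and 116 higher after siKctd10 at D2, and of 1833 that fell, 113 were higher and 9 lower. These classes share the D2 siControl libraries with the siKctd10 comparison, so chance values of those libraries enter both. The slope of the interaction on the mean differentiation change, which is free of such a link only where both siRNA arms are equally noisy, was -0.056, and 0.006 without both siKctd10 libraries numbered 3. The arms were not equally noisy, since the chi-square per gene between replicates reached 63.19 in siKctd10 and 18.19 in siControl. A noisier siKctd10 arm pushes this slope upward, so that noise does not account for a value below 0. The excess in chi-square came from pairs with the siKctd10 libraries numbered 3 (31.48 to 63.19), while the siKctd10 pairs without them gave 14.52 at D0 and 17.10 at D2. Without these libraries the siKctd10 means rested on fewer libraries than the siControl means, which also pushes the 0.006 upward.

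Genes with a match to the siKctd10 guide seed were compared with other genes. Kctd10, which holds the match itself, was left out. The 159 genes with the 7-base match GACGATA in a 3' UTR had a median log2 fold change of -0.11 at D0, against 0.05 in 11877 genes without it. The difference of -0.16 had a two-sided permutation p of 0.0001, the smallest that 10000 permutations give, and none of 778 other 7-base words was as low. At D2 the difference was -0.08 (permutation p = 0.0001). Among single-transcript genes it was -0.34 at D0 and -0.29 at D2 over 31 genes with the match. Of 123 genes lower at D0 with an annotated 3' UTR, Kctd10 left out, 12 (9.76%) held the match, against 1.33% of all genes, among them Mboat1, Cd164, Ube2j1 (-1.58) and Hspd1 (-1.18). Of 239 such genes lower at D2, 10 (4.18%) held it. Among higher genes 3 of 190 (1.58%) held it at D0 and 2 of 361 (0.55%) at D2. The corresponding word of the siControl seed, TTTTCTG, gave a difference of 0.05 at D0 (permutation p = 0.68) and 0.05 at D2 (permutation p = 0.16). Of 469 other 7-base words, 95.7% were as low at D0 and 96.8% at D2. Over single-transcript genes these shares were 90.7% and 68.6%. Repression through the siControl seed would raise this difference, so it was not excluded.

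**Figure D4:**
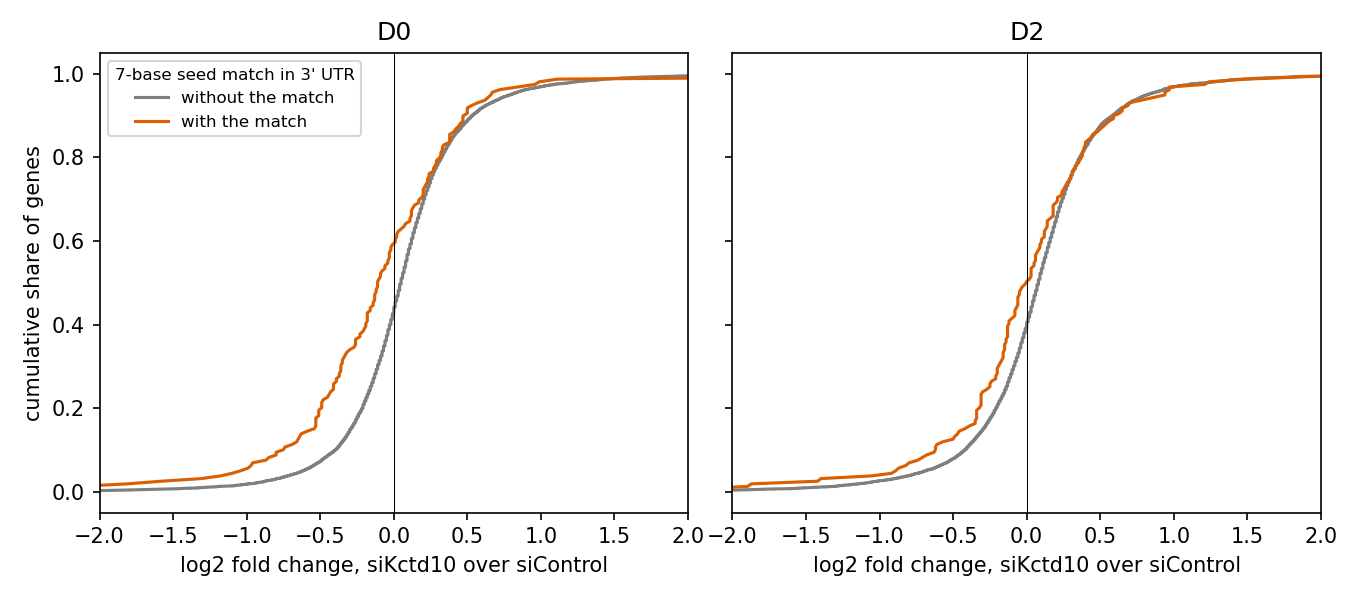
Cumulative share of genes over the log2 fold change, siKctd10 over siControl, at D0 and D2 for genes with and without the 7-base seed match in a 3' UTR, Kctd10 left out, drawn between -2 and 2. At D0 the median was -0.11 with the match and 0.05 without.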

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

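The tests of library and transcript effects on the muscle genes were chosen only after the result was seen, as was the count over splits without both siKctd10 libraries numbered 3, while the other counts over splits of the samples were planned.

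The effect of siKctd10 differed between D0 and D2, by the interaction test of limma, for 101 genes. Among the 6 with the smallest adjusted p in each direction, the interaction was 1.39 for Kcnj2, 1.64 for Adamtsl5, 2.02 for 2410015M20Rik and 1.72 for Tpp1, each with 2 transcripts, and 1.63 for Sfrp2 and 1.59 for Cxcl5, which have a single transcript. It was -1.56 for Ccn2, which rose after siKctd10 at D0 and fell at D2, -2.15 for Dpt and -1.60 for Ccn3, all with a single transcript, and -1.22 for Pde2a and -3.54 for Tmod1, with 7 and 2 transcripts. The gene AC149090.1 was listed at 0 in the other 9 libraries and at 9.46, 8.58 and 6.57 TPM in the D2 siControl libraries, so its fitted value of -3.19 depends on the pseudocount and is not a fold. Acta1, which has 2 transcripts, had an interaction of -1.53, with a siKctd10 effect of 0.94 at D0 and -0.59 at D2.

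The interaction test also called 9 lists. The medians were -0.75 for sarcomere (adjusted p = 0.052 with an estimated correlation), -0.60 for excitation-contraction and neuromuscular junction (adjusted p = 0.015 with an estimated correlation), -0.41 for myogenic transcription factors (adjusted p = 0.052 with an estimated correlation) and -0.57 for muscle metabolism (adjusted p = 0.00031, and adjusted p = 0.12 with an estimated correlation). Smooth muscle markers had a median of -0.47 (adjusted p = 1.3e-05, and adjusted p = 0.015 with an estimated correlation), and their rise with differentiation was 0.66 in siKctd10 against 1.54 in siControl. Their median effect of siKctd10 was 0.70 at D0 and 0.33 at D2, so as a list they were not below siControl at D2. Cholesterol synthesis had -0.39 (adjusted p = 1.3e-06, and adjusted p = 0.12 with an estimated correlation), cell cycle exit -0.21 (adjusted p = 0.017, and adjusted p = 0.12 with an estimated correlation), p53 targets 0.32 (adjusted p = 0.005, and adjusted p = 0.12 with an estimated correlation) and Notch pathway -0.19 (adjusted p = 0.005, and adjusted p = 0.19 with an estimated correlation). The median effect of siKctd10 on cholesterol synthesis was 0.48 at D0 and 0.13 at D2, so that list was not below siControl at D2 either. Members called were 1 lower for smooth muscle, 2 lower for cholesterol synthesis, 1 lower for cell cycle exit, 1 higher and 1 lower for p53 and none for Notch or muscle metabolism. Adjusted over the list alone these were 3 lower, 5 lower, 1 lower, 4 higher and 1 lower, 3 lower and 4 lower.

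For the lower muscle genes at D2, over 90 members of the sarcomere, myogenic, excitation-contraction and metabolism lists the median log2 fold change, less that of all genes, was -0.55 (bootstrap SE 0.11), and it was -0.66 (SE 0.17) over the 31 single-transcript members, which argues against jumping transcript estimates. It was -0.44 (SE 0.12), -0.59 (SE 0.10) and -0.66 (SE 0.08) without the D2 siKctd10 library numbered 1, 2 and 3. These values argue against any 1 of these libraries as the whole cause. The sarcomere mean of log2(TPM + 1) was lowest in the library numbered 1 (4.09, against 4.60 and 4.77). Only 1 of the 90 members held a 6-base match to the guide seed in a 3' UTR. That count argues against direct repression of these genes through such matches. The median over the other 89 members was -0.54 (SE 0.11), which decides nothing, because leaving out 1 member could hardly move it. These SEs come from resampling the genes, which are not independent (estimated correlation 0.163 in the sarcomere list), and do not measure the spread between libraries. An indirect effect of other genes with a seed match cannot be told apart from the loss of Kctd10, because the design holds only 1 siRNA against Kctd10. A role of Kctd10 in the muscle programme may therefore be one open explanation, as a hypothesis.

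For the counts of genes, splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05, and only 1 of the 10, the real one, gave as many genes in each comparison. The real counts were 320 at D0 (highest other split 7), 622 at D2 (7), 4636 for differentiation in siControl (4) and 4755 in siKctd10 (3). For the interaction, 2 of 100 splits of the siRNA labels within days gave at least 101 genes, the real split and a mirrored split. The latter keeps the real labels at D0 and mirrors them at D2, which adds the effects of both days and gave 1082 genes, a structure of the samples. The highest count without these was 57. Other splits break up the siRNA effect of each day, not only its difference between days. They therefore cannot tell whether equal effects on both days would give 101 genes by chance. For the correlation of D0 and D2 effects, 2 of 100 splits, the real one and the same mirrored one, reached 0.2 in absolute size (highest without them 0.17). Labels assigned at random were thus excluded as its source with all libraries in. This tests against no siRNA effect, not against unrelated effects on the 2 days. The siKctd10 libraries numbered 3 were the only same-numbered pair that correlated over 0.1 (0.20). Without both, the correlation was 0.12, and only 1 of the 100 splits of the 10 libraries left, the real one, gave as large a value (highest other 0.1), so labels assigned at random were excluded there too. For the differentiation slope of -0.056, 8 of 100 splits were as large (highest other 0.085), so chance was not excluded.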

How the results depend on the processing

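Single-transcript genes only, and leaving out both siKctd10 libraries numbered 3, were chosen only after the data were seen, and other settings were planned. No named gene or list that passed its test changed sign in any setting run. Over the planned settings, named genes stayed on their side of the threshold in 6252 cases, lost their call in 509 and gained one in 39, and lists in 2670, 72 and 30. Over the added settings these were 391, 39 and 11 for genes and 207, 9 and 8 for lists. With an estimated correlation, the gene lists called at D0 numbered 2, gene lists called at D2 0, gene lists called for differentiation in siControl 7 and gene lists called for the interaction 2, and fry called 19 for differentiation in siControl. The number of genes with a day by siRNA interaction was 66 with a pseudocount of 0.1, 168 with a pseudocount of 5, 156 with FPKM in place of TPM and 64 without both siKctd10 libraries numbered 3. With only the groups compared in the fit, 72 genes changed by siKctd10 at D0 and 263 genes changed by siKctd10 at D2, with fewer libraries behind the spread. At an absolute log2 fold change of at least 1 the counts were 69 at D0, 160 at D2, 1799 and 1829 for differentiation in siControl and siKctd10 and 63 for the interaction, by construction fewer. Over the 4025 single-transcript genes, by construction fewer genes tested, 396 changed at D2, genes changed by differentiation in siControl numbered 1867 and genes changed by differentiation in siKctd10 1943, and the correlation of siKctd10 effects at D0 and D2 was 0.32. Without both siKctd10 libraries numbered 3 the correlation was 0.12 and the differentiation slope turned from -0.056 to 0.006. Apart from these constructions the cause was not tested. Kctd10 has 2 transcripts, so it has no value among single-transcript genes.

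Leaving out 1 library at a time gave 118 to 306 genes changed by siKctd10 at D0, 316 to 683 genes changed by siKctd10 at D2, 57 to 84 genes with a day by siRNA interaction, 7 to 11 gene lists called at D2 and a differentiation slope of -0.092 to -0.016. The interaction count was 57 without the D0 siControl library numbered 1, 59 without the D0 siKctd10 library numbered 1, 61 and 63 without the D2 siControl libraries numbered 2 and 3 and 58 without the D2 siKctd10 library numbered 1. Gene lists called at D2 fell to 7 without the D2 siControl library numbered 2, where myoblast fusion, oxidative phosphorylation, proliferation and ER stress and ATF4 lost their calls. Fusion also lost its call without the D2 siKctd10 library numbered 1 or 3, oxidative phosphorylation without number 2, proliferation without number 2 or 3 or the D2 siControl library numbered 3, and ER stress and ATF4 without those 3 libraries or the D0 siKctd10 library numbered 1 or 2. The Kctd10 level, D0, stayed between -3.53 and -3.38 and the Kctd10 level, D2, between -3.18 and -2.99. The cause was not tested. Values that start from estimates without read counts limit what depth can show, and in simulated data 43.5% of log2 changes of 1 at D0 were recovered.

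Replicate numbers are shared by the labels, but nothing says that they pair the samples, and whether they do is not settled. Same-numbered libraries correlated between -0.02 and 0.20, over 0.1 in 1 of 18 pairs, and 7 of 12 libraries correlated best with their own number. Some would do so by chance, and that number was not computed, so the count of 7 does not settle pairing. The highest values were between the D0 and D2 siKctd10 libraries (0.09, 0.04 and 0.20 for numbers 1, 2 and 3), against at most 0.03 in other pairs. Structure shared by number in the siKctd10 arm was therefore not excluded. With the replicate number as a block 45 genes had an interaction, and no other count of genes or lists moved by over 1.5 times.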

Other observations

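The tests of how far seed matches and jumping transcript estimates account for whole sets of genes were chosen only after the result was seen, while the test of the seed itself was written before.

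None of 32 genes of the KCTD family and CUL3 ligase list passed at D0 (adjusted p = 0.83), and at D2 Klhl22 (0.62) and Spop (0.79) rose (2 rose and 1 fell adjusted over the list alone, adjusted p = 0.23 by camera and 0.0071, upward, by fry). Among 29 genes of integrins and focal adhesion, Itga4 fell at D2 from 40.4 ± 4.31 to 10 ± 1.41 TPM (-1.91, 5 transcripts) and Itga3 rose (0.87), with 1 higher and 3 lower in all (2 and 4 adjusted over the list alone, adjusted p = 0.97), although the median of 0.22 was above 0 and the test pointed down. At D2 the protrusive and branched actin list had Capza1 and Cfl2 (-0.50, which holds the 7-base seed match of the siKctd10 guide) lower (2 adjusted over the list alone, adjusted p = 0.47), with a median of 0.05 and a mean of -0.03. Rhob at D2 did not pass (-0.36, adjusted p = 0.057).

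Other lists gave single genes. The interferon target Gbp2 rose at D0 (1.06) and D2 (0.83), and Ifit1 of the same list fell at D2 (-0.62), with 1 of 22 members higher at D0 and 1 higher and 1 lower at D2 (3, and 3 and 2, adjusted over the list alone, adjusted p = 0.62 and 0.47). Among 23 p53 targets Plk2 (-0.38) and Phlda3 (-0.38) fell at D0 (3 adjusted over the list alone, adjusted p = 0.46), while at D2 2 were higher and 1 lower (7 and 1 adjusted over the list alone, median 0.29, adjusted p = 0.062 by camera and 0.0023, upward, by fry). Among 15 cell cycle exit genes Ccnd2 rose at D0 (0.39, 4 adjusted over the list alone, adjusted p = 0.35 by camera and 0.023, upward, by fry). The Notch target Hey1 fell at D2 (36.7 ± 2.93 to 18.7 ± 1.78 TPM, -0.94, with 3 of 14 list members lower adjusted over the list alone, adjusted p = 0.13). Among 15 TGF beta and BMP genes Grem1 rose (0.48) at D2 (1 higher and 1 lower in all, 1 and 1 adjusted over the list alone, adjusted p = 0.98). Of markers of other cell types, Cebpa (1.03) and Plin4 (0.89) of 5 adipocyte markers rose at D2 and 1 fell (2 and 1 adjusted over the list alone, adjusted p = 0.39 by camera and 0.0023, upward, by fry), Phex (0.70) of 5 osteoblast markers rose (1 adjusted over the list alone, adjusted p = 0.85), none of 3 macrophage and leukocyte markers passed (adjusted p = 0.62), and Tubb3 of 2 endothelial and neural markers fell (-0.39, 1 adjusted over the list alone, adjusted p = 0.36). For siKctd10 and its interaction with day, the remaining lists that fry called and camera did not were excitation-contraction and neuromuscular junction at D0 (adjusted p = 0.016 by fry, upward, 1 higher, 4 adjusted over the list alone), ER stress and ATF4 at D0 (adjusted p = 0.023 by fry, upward) and YAP and TEAD targets for the interaction (adjusted p = 0.0011 by fry, downward, 1 lower, 1 adjusted over the list alone). Against the direction by fry, the only ER stress and ATF4 member past the threshold at D0, Atf3, fell (-0.85, 3 transcripts, with 2 higher and 1 lower adjusted over the list alone). None of 5 mitochondrially encoded genes passed at D0 (adjusted p = 0.13) or D2 (adjusted p = 0.47).

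Genes lower after siKctd10 at D0 were weighed for off-target repression. Genes with the 7-base seed match were lower by a median of -0.16 (permutation SD 0.027), so seed repression may contribute, including to Mboat1, Cd164 and Ube2j1. As the direct cause of all these falls, through matches in 3' UTRs, it is argued against. Of the lower genes with an annotated 3' UTR, Kctd10 left out, 13.8% (17 of 123, exact 95% interval 8.3 to 21.2%) held even the 6-base match, against 5.6% of all genes. Falls downstream of genes with a match cannot be told apart from the loss of Kctd10 with 1 siRNA. The excess over chance was 10.4 genes with the 7-base match. Matches outside 3' UTRs, and matches to the seed of the other siRNA strand, were not tested.

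Changes of 2-fold or more at D0 were weighed for jumping transcript estimates. Of 55 such genes with mean TPM of at least 5, 27 (49.1%, exact 95% interval 35.4 to 62.9%) had a single transcript, where no jump between transcripts can arise. This argues against such jumps as the whole cause, although 6.92% of single-transcript genes also spread more than 3-fold inside some group. The share was 28.0% in other genes (two-sided Fisher exact p = 0.0013). That excess cannot be weighed, because single-transcript genes vary less between replicates and are called more easily. Their median residual SD on the log2 scale was 0.162, against 0.278 for genes with several or overlapping transcripts. A spread of more than 3-fold inside some group was seen in 10.9% of the 55 (6 genes) and in 21.4% of 10276 others (two-sided Fisher exact p = 0.068). That comparison decides nothing, because a spread inside a group keeps a gene from being called. Jumps may therefore still account for single genes with several transcripts, such as Ppia and Sp1.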
